A study of Arabidopsis thaliana with 6 samples.

How the data were processed

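The series holds 6 Affymetrix ATH1 arrays of whole Arabidopsis seedlings, 7 days old, grown at 20 °C on MS medium after 4 days of stratification at 4 °C. Plates were moved to 20 °C or 4 °C in the light for 3 h before harvest. Each array received biotin-labelled cRNA from the RNA of 40 to 60 pooled plants, with 1 array for each of the wild type, sfr6 and cls8 at each temperature. Per the labels, each array carries 22810 probe sets. The deposited values are intensity on a linear scale, and on each array the mean of the values, with the lowest and highest 2% left out, is 100. This scaling was found from the values and is not described in the labels. The algorithm, software and version behind these values are not given in the sources used here. Detection calls were not used here. The arrays' number, not a count of molecules, limits the precision.

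Of the 22810 probe sets, 64 controls were set aside, which left 22746. The values were transformed as log2 of the intensity plus a pseudocount of 14.1, the 25th percentile of all values, and 13648 probe sets were kept whose mean log2 value lay at or above the 40th percentile. A table of the platform's probes gave exactly 1 gene for 13513 probe sets, several genes for 503 and no gene for 8730. Only probe sets with 1 gene were named as genes, and 13436 of the 13513 matched a RefSeq gene table of the TAIR10.1 assembly, which was used for names alone. Of the kept probe sets, 7343 had exactly 1 gene. Genes without a named probe set were not analysed here. Members of gene lists are called measured where their named probe set was also kept by the filter. The build behind the probe table is not given in the sources used here, so that no coordinates are printed.

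The comparisons used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) with additive terms for line and temperature, which left 2 residual degrees of freedom beside a prior of 6.82. Temperature was compared over 3 lines, and sfr6 and cls8 were each compared with the wild type over 2 temperatures. All tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the 13648 probe sets, with a threshold of 0.05. The residual of this model holds array noise and any response to cold that differs between lines. The 2 mutant comparisons share the wild-type arrays and were not compared with each other.

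Gene lists with at least 3 kept members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 22 lists in each comparison, 66 tests in all. The lists of the CBF regulon, nuclear photosynthesis genes, plastid and mitochondrion transcripts and tissue markers were chosen before the data were examined. So were the main tests, the filter, the pseudocount, the rule for named genes and most of the alternatives. The fits without both arrays of the third line for the sfr6, cls8 and list tests were chosen after seeing the data. Further gene families were added after the probe annotation was seen and before the values of the plant genes were examined. Folds within a line, and their differences between 2 lines, had no residual degrees of freedom and are given as values. A cold term of its own for 1 line, set against the mean of the others with 1 residual degree of freedom, was added after seeing the data. The median of a list was set against 10000 random lists of the same size, matched on mean level in 20 bins.

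The rule for named genes took the 12 largest rises and the 12 largest falls for temperature, and up to 10 of each for each mutant, among probe sets with 1 gene that passed the threshold and moved the same way in every pair. For differences between lines it took, among genes changed at least 4-fold in the wild type, up to 10 with the largest reduction and 5 with the largest increase, and it also took any member of the chosen lists. No named gene of the sfr6 comparison met the rule for an increase. Unnamed probe sets are given as the 2 largest rises and the 2 largest falls of each comparison.

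The model was tested on simulated data with variances drawn from the fitted prior. For temperature, 40% of changes of 0.5 on the log2 scale were recovered (20 of 50), and all 45 of 1, all 41 of 1.5 and all 42 of 2. For sfr6, 8.16% of changes of 0.5 were recovered, 80.9% of 1, 97.8% of 1.5 and 100% of 2. For cls8, 23.4% of changes of 0.5 were recovered, and 100% of 1, 1.5 and 2. Unchanged probe sets made up 14 of 162 calls for temperature, 3 of 135 for sfr6 and 1 of 148 for cls8. Each comparison was simulated once, with the same layout for sfr6 and cls8, so the gap between their shares is not a difference in power. Fewer probe sets were changed than passed for temperature in the data, which moves the adjusted threshold. No simulated response to cold differed between lines, so these shares need not hold for the data. A shifted list of 20 genes was found at an adjusted p of 3.64e-66, and 0 of 20 unchanged lists were called. The simulated genes varied independently, so this does not show how often lists whose genes vary together are called falsely. The estimated correlation was 0.82 for the measured CBF regulon list and 0.28 for the plastid list.

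The alternatives were no pseudocount, the median of all values (43.6) as the pseudocount, no filter, a filter at the 60th percentile, quantile normalization, centring on the median, eBayes without an intensity trend, no block, an estimated correlation for the lists, and fits without each array or each line.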

Results

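Gene expression was measured in whole Arabidopsis seedlings of 3 lines, each held for 3 h in the light at 20 °C or at 4 °C. The lines were the Col-0 wild type, sfr6, a mutant sensitive to freezing that lacks a subunit of the Mediator complex, and cls8, a mutant sensitive to chilling with a defect in the large subunit of ribonucleotide reductase. Neither of these mutated genes had a named probe set, so both were not analysed here. The stated subject of the series is how chilling and freezing stress act at the molecular level. RNA from 40 to 60 pooled plants, 7 days old, went onto each of the 6 ATH1 arrays. There was 1 array for each line and temperature and hence no replicate within a group, so the number of arrays limits the precision of every value. The array titles mark both cls8 arrays as repeats, so that a repeat run and the cls8 genotype cannot be told apart.

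Every array had the same trimmed mean intensity of 100. The median intensity ranged from 41.7 in cls8 at 4 °C to 45.2 in the wild type at 20 °C. The brightest probe set reached 3744 on the cls8 array at 20 °C and 5895 on the cls8 array at 4 °C. Per the labels, the sfr6 array at 20 °C had 1101 outlier cells and the cls8 array at 20 °C had 922. The other arrays had 406 to 517. The 25S ribosomal RNA control read 481.5 in cls8 at 20 °C, against 2716 in the wild type and 2559 in sfr6 at that temperature. At 4 °C it read 1424 in the wild type, 1665 in sfr6 and 1670 in cls8. In a principal component analysis of the log2 values, 56.1% of the variance lay on a component that separated 4 °C from 20 °C in all 3 lines. A further 22.1% lay on a component that set both sfr6 arrays apart from the other arrays.

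The first comparison asked which transcripts differed between 4 °C and 20 °C in all 3 lines. After 3 h at 4 °C, AT4G33980, COR27 and STZ, all dim at 20 °C, were higher in 3 of 3 lines, as the rule for named genes required. AT4G33980 rose from a mean intensity of 13.5 ± 3.12 (SD, n = 3 arrays) to 372.7 ± 100.3, and COR27, a gene regulated by cold and light, rose from 12.4 ± 1.27 to 243 ± 73.3. STZ, a zinc-finger transcriptional repressor of stress responses, rose from 25.9 ± 3.61 to 240.5 ± 106.1. Transcripts that fell included AT1G23390, an F-box protein with Kelch repeats that controls the turnover of chalcone synthase, from 1379 ± 310.9 to 192.7 ± 36.3. AT3G26510 fell from 508 ± 60.6 to 48.9 ± 16.3.

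In the limma model with line as a block, the fitted log2 difference was 3.78 ± 0.12 (SE) for AT4G33980, with a Benjamini-Hochberg adjusted p of 6.80e-07. COR27 had a log2 difference of 3.24 ± 0.17 (limma adjusted p = 7.98e-06) and STZ one of 2.57 ± 0.19 (limma adjusted p = 4.82e-05). The other 9 named genes that rose were AT4G36010, which encodes a thaumatin-like protein, AT1G11210, AT5G47060, AT1G70420, AT1G51090, AT5G65300, AT5G62360, AT1G53035 and AT5G20790, with log2 differences from 2.26 to 3.37. AT3G26510 had the largest fall of a named gene, at a log2 difference of -3.07 ± 0.13 (limma adjusted p = 2.64e-06), and AT1G23390 fell by 2.74 ± 0.18 on the log2 scale (limma adjusted p = 2.52e-05). The other 10 named genes that fell were AT4G28240, AT2G20670, AT5G03230, AT3G56360, AT5G19120, AT2G32150, AT3G52480, AT3G23880, AT4G10910 and AT3G06070, with log2 differences from -2.82 to -1.79. With no pseudocount, and with the median of all values as the pseudocount, the difference was 4.78 and 2.84 for AT4G33980, 4.26 and 2.32 for COR27, and 3.11 and 1.95 for STZ. Larger rises than these occurred in probe sets that the annotation pairs with no gene. Probe set 254066_at read 17.7 at 20 °C and 1210 at 4 °C in the wild type, with a log2 difference of 5.48 ± 0.10 over the 3 lines, and 254075_at read 16 and 870.8, with a log2 difference of 4.85 ± 0.09. Among the unnamed probe sets that fell, 251443_at had a log2 difference of -2.81 and 253061_at one of -2.48.

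**Figure D1:**
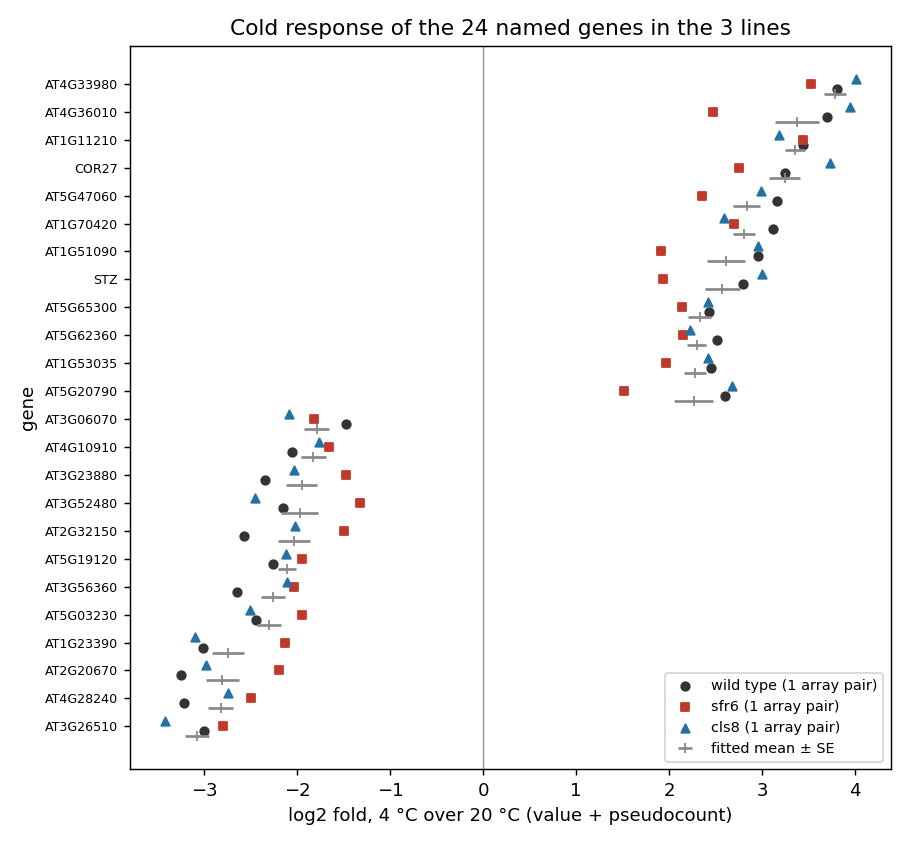
Log2 fold of intensity plus pseudocount at 4 °C over 20 °C for the 24 named genes of the cold comparison, with 1 point per line (1 array pair each) and the fitted mean with its SE in grey. All 12 genes that rose and all 12 that fell lie on the same side of 0 in the 3 lines, as the rule for named genes required.

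Of 13648 probe sets tested with limma, 2570 passed an adjusted p of 0.05 for temperature, with 1308 higher and 1262 lower at 4 °C. The direction was the same in 3 of 3 lines for 2566 of them, and 334 differed at least 2-fold, 202 higher and 132 lower. Without the sfr6 array at 20 °C the count was 1528, without the sfr6 array at 4 °C it was 1533, and with no filter on the mean level it was 1445. With no block for line it was 1589.

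The CBF regulon, the cold-induced COR, KIN and LTI genes under the CBF transcription factors, was higher at 4 °C. Of 16 listed genes, 5 had a named probe set, and 4 of these rose while DI21, at a log2 difference of 0.25, did not pass (5 passed when adjusted over the list alone). COR15A and COR15B, which encode chloroplast proteins that protect membranes during freezing, had log2 differences of 2.16 ± 0.24 and 2.14 ± 0.11, with limma adjusted p of 4.49e-04 and 6.19e-06. The dehydrins LTI30 and COR47 had log2 differences of 1.11 ± 0.15 and 0.70 ± 0.14. The list shifted up against the other probe sets in the camera test of limma (median log2 difference 1.11, adjusted p = 1.39e-04). With an estimated correlation between genes its adjusted p was 0.868, and none of the 11 list calls in the 3 comparisons passed. That setting rests on 2 residual degrees of freedom, so it cannot tell whether correlation between genes undoes a call.

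Single genes of other lists were also higher at 4 °C. ATSPS4F, a sucrose phosphate synthase, had a log2 difference of 0.73 ± 0.14 (limma adjusted p = 0.0072), and the clock gene GI one of 0.36 ± 0.10 (limma adjusted p = 0.0335). DFR, which encodes dihydroflavonol reductase of anthocyanin synthesis, had a log2 difference of 0.63 ± 0.14 (limma adjusted p = 0.0155), while UF3GT of the same pathway had one of 0.09 and did not pass. Among 69 plastid-encoded transcripts, rps16 rose by a log2 difference of 1.06, rbcL by 0.47 and atpH by 0.42, and 66 did not pass. Only 1 passed when adjusted over the list alone. The log2 fold of rbcL was 0.28 in the wild type, 0.28 in sfr6 and 0.84 in cls8. As a list the plastid transcripts had an adjusted p of 0.151 in the camera test of limma. None of the 4 nuclear-encoded photosynthesis genes measured (RCA, LHCB4.1, LHCB4.2 and PSBW) passed for temperature, and their list had a median log2 difference of -0.11 (camera adjusted p = 0.885).

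Markers of root tissue (PYK10 and EXPA7), guard cells (FMA) and dividing cells (AUR1) were measured because whole seedlings can differ in their share of tissues. They were the only kept members of lists of 12 root, 5 leaf epidermis, guard cell and myrosin cell, and 8 cell division genes. Of 11 seed genes 0 were kept. None of these 4 markers passed limma for temperature or for either mutant, but so few markers say little about shares of tissues. Their log2 differences for temperature lay between -0.34 for AUR1 and 0.09 for PYK10. In sfr6 against the wild type they lay between -0.30 for AUR1 and -0.01 for PYK10, and in cls8 between -0.19 for EXPA7 and 0.03 for FMA. For PYK10 in cls8 the difference was -0.37 at 20 °C and 0.26 at 4 °C.

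The sfr6 comparison asked which transcripts differed between sfr6 and the wild type at both temperatures. More transcripts passed as lower in sfr6 (133 probe sets) than as higher (50). AT5G62360, of the family of invertase and pectin methylesterase inhibitors, read 102 in the wild type and 7.3 in sfr6 at 20 °C, and 647 and 80.5 at 4 °C. The plant defensin PDF1.2 read 62 and 1.8 at 20 °C, and AT1G66100, a thionin, read 903.1 and 281.6. ICL, which encodes isocitrate lyase of the glyoxylate cycle, was higher in sfr6, at 226.8 against 20.8 at 20 °C and 270.2 against 30.8 at 4 °C. AT1G47400, a peptide induced by iron deficiency, read 270.9 in sfr6 and 119.7 in the wild type at 20 °C.

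In limma, AT5G62360 had a log2 difference between sfr6 and the wild type of -2.62 ± 0.13 (SE, adjusted p = 8.04e-05). It was lower in 2 of 2 temperature pairs, as the rule for named genes required. The thionin AT1G66100 had a log2 difference of -1.95 ± 0.19 (limma adjusted p = 0.0019) and the dehydrin LTI30 one of -1.91 ± 0.18 (limma adjusted p = 0.0019). PDF1.2 had a log2 difference of -2.01 ± 0.29 (limma adjusted p = 0.013). PDF1.2b, the other member of the jasmonate and ethylene defence list that the filter kept, had one of -1.98 and did not pass (limma adjusted p = 0.0878). The other 6 named genes that were lower were AT3G28220, AT3G45160, AT2G16005, AT1G67865, AT5G37990 and AT1G52000, a jacalin-like lectin, with log2 differences from -2.08 to -1.77. ICL had a log2 difference of 2.73 ± 0.32 (limma adjusted p = 0.0048) and AT1G47400 one of 1.46 ± 0.18 (limma adjusted p = 0.0058). The other 8 named genes that were higher were AT1G29090, AT5G10580, GSTU22, a tau-class glutathione transferase, AT1G62290, AT2G41410, a protein with calcium-binding EF hands, AT4G23680, AT5G01870, a lipid transfer protein, and AT3G01260, with log2 differences from 0.82 to 1.47. With no pseudocount, and with the median as the pseudocount, AT5G62360 had a difference of -3.41 and -1.996, and ICL one of 3.29 and 2.07. PDF1.2, which read 1.8 in sfr6 at 20 °C, had one of -1.10 with the median as the pseudocount and no longer passed. The unnamed probe sets with the largest falls were 265561_s_at at -2.91 and 248377_at at -2.79, and those with the largest rises were 248125_at at 1.35 and 264777_at at 1.24.

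**Figure D2:**
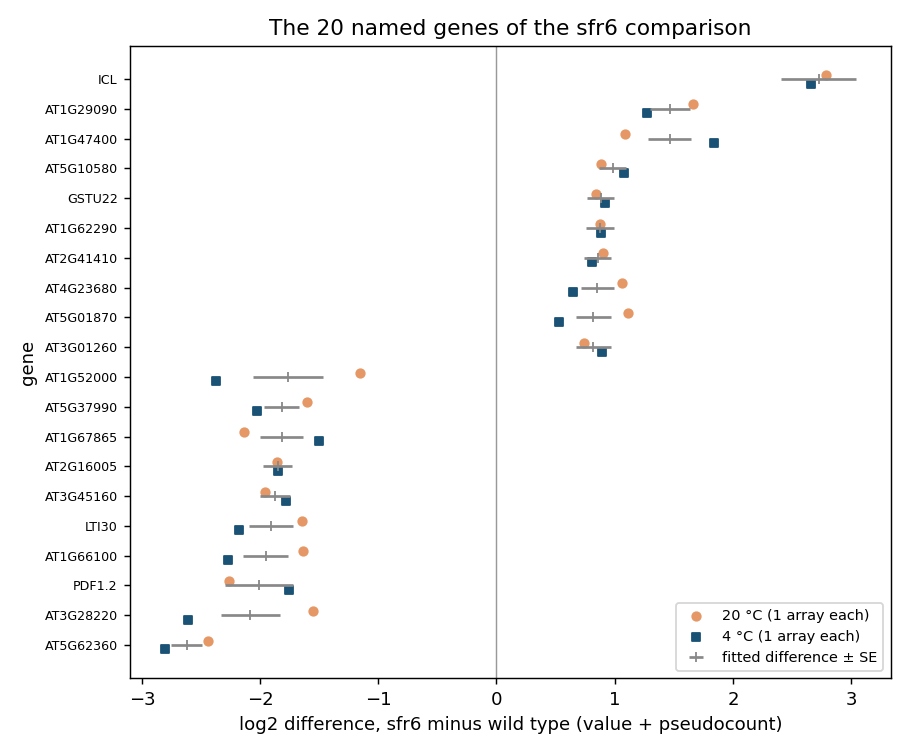
Log2 difference of intensity plus pseudocount between sfr6 and the wild type for the 20 named genes, with 1 point at 20 °C and 1 at 4 °C (1 array per line and temperature) and the fitted difference with its SE in grey. The 10 genes that were higher and the 10 that were lower lie on the same side of 0 at both temperatures. The rule for named genes required this.

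In all, 183 of 13648 probe sets passed limma for sfr6, with 50 higher and 133 lower, and 81 of these differed at least 2-fold, 10 higher and 71 lower. All 183 had the same direction at both temperatures. The count was 65 without the sfr6 array at 4 °C, 409 without the cls8 array at 20 °C and 411 without the cls8 array at 4 °C. It was 18 with no filter on the mean level and 0 with no temperature term, where 524 probe sets had an unadjusted p under 0.05. In every fit with arrays left out, 8 of the 10 named lower genes passed, among them AT5G62360, AT1G66100 and LTI30, but only 2 of the 10 higher ones, ICL and AT1G29090. AT1G47400 was lost without the sfr6 array at 4 °C, and PDF1.2 without either sfr6 array.

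The CBF regulon was lower in sfr6. COR15B and LTI30 fell, at log2 differences of -0.75 (limma adjusted p = 0.0321) and -1.91, and the 3 other members did not pass over all probe sets, with COR15A at -1.16, COR47 at -0.67 and DI21 at -0.16 (4 of 5 passed when adjusted over the list alone). The list had a median log2 difference of -0.75 (camera adjusted p = 7.59e-06), and its adjusted p was 0.704 with an estimated correlation. Single members of other families also differed in limma. XTH16, a xyloglucan endotransglucosylase of the cell wall, was lower at -0.84 (adjusted p = 0.0202), PORB, a protochlorophyllide oxidoreductase, was lower at -1.04 (adjusted p = 0.028), and the alpha-tubulin TUA1 was higher at 0.70 (adjusted p = 0.0318).

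How far each line responded to the cold was described with values alone, because each fold came from 1 pair of arrays. COR15A rose in intensity from 48.4 to 423.7 in the wild type, from 33.2 to 101.3 in sfr6 and from 97.2 to 573 in cls8. LTI30 read 365.9 and 847 in the wild type, 107.6 and 176.7 in sfr6, and 366.7 and 1074 in cls8. COR15B read 110 and 619.1 in the wild type, 71.1 and 313.7 in sfr6, and 171.5 and 793.6 in cls8. The median log2 fold of the 5 CBF regulon members was 1.18 in the wild type, 0.65 in sfr6 and 1.51 in cls8. The fold of each of the 5 was smaller in sfr6 than in the wild type, by a median of -0.44 on the log2 scale. This lay at the 0.15 percentile of 10000 random lists matched on level, though these were not picked for a response to cold. Among random sets of 5 from other probe sets raised at least 2-fold in the cold in cls8, the same median lay at the 9.85 percentile. The 4 histone H2B genes measured (HTB1, HTB2, HTB4 and HTB11), picked after their values were seen, also had smaller folds in sfr6 than in the wild type, at 0.79 against 1.37 for HTB1. The whole list of 7 histone genes had a median of -0.50 for sfr6 minus the wild type, at the 0.03 percentile, with 6 of 7 smaller. For cls8 minus the wild type the median of the CBF regulon was 0.12, at the 75.7 percentile, and it was -0.06 after quantile normalization.

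**Figure D3:**
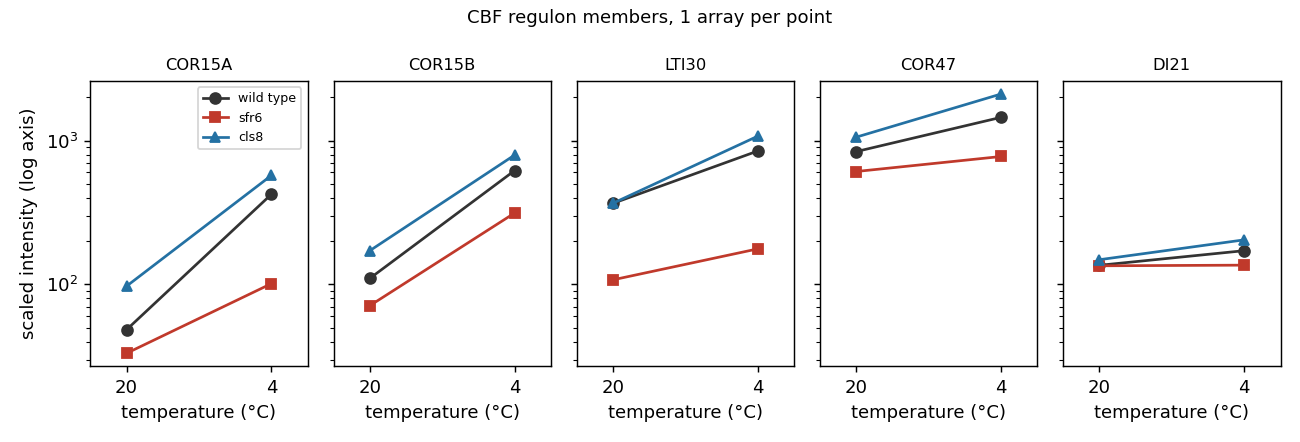
Scaled intensity on a log axis at 20 °C and 4 °C for the 5 measured members of the CBF regulon, with 1 array per point and 1 line per genotype. The sfr6 points lie lowest in all 5 panels, for example at 101.3 for COR15A at 4 °C against 423.7 in the wild type and 573 in cls8.

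Among named genes that changed at least 4-fold in the wild type, the largest reductions of the fold in sfr6 were those of AT1G68500, AT4G39675 and COR15A. AT1G68500 read 52.6 at 20 °C and 456.7 at 4 °C in the wild type, 18.4 and 38.2 in sfr6, and 39.7 and 445.6 in cls8. AT4G39675 read 196.9 and 26.6 in the wild type and 64.3 and 30.7 in sfr6. The 10 with the largest reductions also included AT4G36010, AT5G46710, AT5G20790, AT2G32150, AT2G20670, AT1G51090 and AT1G23390. For cls8 the 10 with the largest reductions were AT4G39675, AT2G32150, AT3G56360, AT1G70420, AT5G50450, AT4G28240, COR15A, AT3G23880, AT5G46710 and AT4G10910, and the 5 with the largest increases were COR27, AT3G26510, AT3G52480, AT1G68500 and AT4G36010. Genes picked by a large fold in the wild type tend to have a smaller one elsewhere, so these reductions were not read as a test. At least 2-fold, 282 probe sets were higher and 196 lower at 4 °C in the wild type, 256 and 130 in sfr6, and 236 and 170 in cls8, with 120 higher and 62 lower in all 3 lines. The totals of 478, 386 and 406 were 711, 597 and 626 with no pseudocount, and 282, 216 and 229 with the median of all values as the pseudocount. The folds correlated across probe sets, which are not independent replicates, at r = 0.719 between the wild type and sfr6 and at r = 0.708 between the wild type and cls8.

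The cls8 comparison asked which transcripts differed between cls8 and the wild type at both temperatures. A few nuclear transcripts were higher in cls8, and 3 plastid-encoded transcripts were lower. AT2G15560 read 362.7 in cls8 and 29.9 in the wild type at 20 °C, and 270.5 and 17.9 at 4 °C. QQS, a gene that affects starch content, read 291 and 49.5 at 20 °C, and AT5G26270 read 1196 and 295.3. The plastid transcript ndhF, of the NADH dehydrogenase-like complex, read 29.4 in cls8 and 87.5 in the wild type at 20 °C, and LCR68, a small cysteine-rich protein of the defensin type, read 351.7 and 882.1.

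In limma, AT2G15560 had a log2 difference of 3.13 ± 0.15 (SE, adjusted p = 5.16e-05). It was higher in 2 of 2 temperature pairs, as the rule for named genes required. QQS had a log2 difference of 2.33 ± 0.14 and AT5G26270 one of 2.12 ± 0.13, each with a limma adjusted p of 2.04e-04. AT5G03090, AT5G15360 and AT2G16000 had log2 differences of 1.56, 1.39 and 1.29. LCR68 was lower at -1.39 ± 0.13 (limma adjusted p = 0.0069), ndhF at -1.22 ± 0.13 (limma adjusted p = 0.0158) and AT1G18270 at -1.19 ± 0.16 (limma adjusted p = 0.0376). The plastid transcripts psbT, of photosystem II, and petG, of the cytochrome b6f complex, were lower at -1.17 and -1.06. The unnamed probe set 266680_s_at read 1.8 and 0.7 in the wild type and 324.4 and 262.1 in cls8 at 20 °C and 4 °C, with a log2 difference of 4.32 ± 0.15, whose size depends on the pseudocount of 14.1 because the wild-type values lie below it. With no pseudocount, and with the median as the pseudocount, AT2G15560 had a difference of 3.76 and 2.41, and QQS one of 2.81 and 1.77. Of the other unnamed probe sets, 258856_at was higher at 1.39, and 267545_at and 244990_s_at were lower at -1.25 and -1.09. In all, 16 probe sets passed limma, 9 higher and 7 lower, and 873 had an unadjusted p under 0.05. The count was 27 without the cls8 array at 4 °C, 4 with no filter on the mean level, 9 with a filter at the 60th percentile and 1 with no temperature term. Of the 11 named genes, 8 passed in every fit with arrays left out, while petG was lost without the cls8 array at 20 °C, AT2G16000 without the cls8 array at 4 °C and AT1G18270 in 5 of 7 such fits.

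Of the 69 plastid-encoded transcripts, 3 were lower in cls8 (ndhF, psbT and petG), none was higher and 66 did not pass over all probe sets, while 16 passed when adjusted over the list alone. The list had a median log2 difference of -0.31 (camera adjusted p = 5.41e-26), and its adjusted p was 0.414 with an estimated correlation. The median was -0.29 for 26 photosystem and cytochrome subunits, -0.45 for 10 NDH subunits, -0.23 for 6 ATP synthase subunits and -0.32 for 19 ribosomal proteins and RNA polymerase subunits. Their camera adjusted p were 1.27e-13, 7.82e-09, 0.0124 and 1.45e-10, and all 4 had an adjusted p of 0.414 with an estimated correlation. Of 23 mitochondrion-encoded probe sets, only 7 were kept by the filter on the mean level. These 7 had a median of -0.27 with no member passing (camera adjusted p = 5.86e-04, and adjusted p = 0.414 with an estimated correlation). The 25S ribosomal RNA control of cls8 was at 0.177 of the wild type at 20 °C and at 1.17 of it at 4 °C. At 20 °C 68 of the 69 plastid transcripts were lower in cls8, with a median of -0.56, and at 4 °C 46 of 69 were lower, with a median of -0.12. In sfr6 54 of 69 were lower than in the wild type at 20 °C, with a median of -0.14, and 26 of 69 at 4 °C, with a median of 0.05. The ratio of the 3' to the 5' actin control, a sign of RNA quality and labelling, was 2.79 in cls8 at 20 °C and 5.53 at 4 °C, against 3.79 and 3.73 in the wild type and 5.14 and 4.199 in sfr6. The GAPDH control differed less between the cls8 arrays, at 1.27 and 1.23, against 1.77 and 1.31 in the wild type and 1.2 and 1.23 in sfr6. For the ubiquitin control the ratio was 2.25 and 2.97 in cls8, 3.08 and 2.59 in the wild type, and 3.07 and 2.98 in sfr6. The 5 CBF regulon members had a median log2 difference of 0.43 in cls8 with none passing over all probe sets (camera adjusted p = 0.0011, and adjusted p = 0.575 with an estimated correlation), and 1 passed when adjusted over the list alone.

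**Figure D4:**
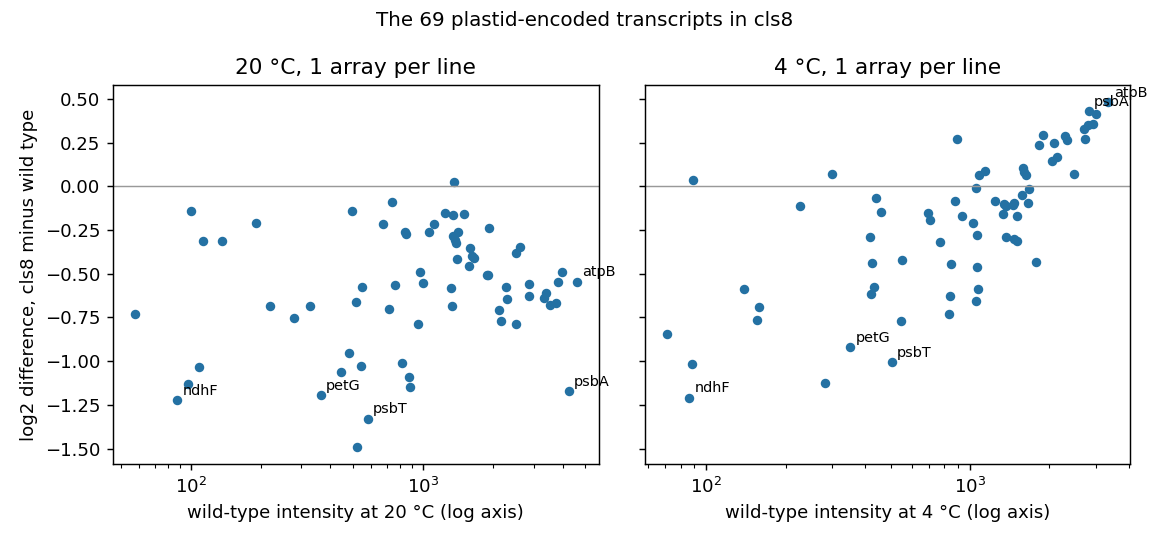
Log2 difference of intensity plus pseudocount between cls8 and the wild type for each of the 69 plastid-encoded transcripts, against its wild-type intensity on a log axis, with 1 array per line at 20 °C and at 4 °C. At 20 °C 68 of the 69 points lie below 0, and at 4 °C 46 of them do, with the brightest transcripts above 0.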

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

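The tests of an own cold response of a line and the comparison with other bright probe sets were chosen after the results were seen.

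A model with a separate cold term for 1 line left 1 residual degree of freedom, and 2 probe sets passed it in limma, both for cls8. PDF1.2b, a plant defensin, had a cold response larger in cls8 than the mean of the other lines by 2.17 ± 0.29 on the log2 scale (limma adjusted p = 0.0345), with intensities from 190.7 to 105.4 in the wild type, from 25.9 to 25.3 in sfr6 and from 108.2 to 402.1 in cls8. Its probe set is of a type that can cross-hybridise with related genes. Probe set 261226_at, without a gene in the annotation, differed by 2.11 ± 0.27 (limma adjusted p = 0.0345), with intensities from 223 to 79.5 in the wild type, from 272.1 to 58.3 in sfr6 and from 121.3 to 170.6 in cls8. The cls8 term rests on 1 pair of arrays with no spread of its own, and the residual comes from the wild type and sfr6 pairs, so the cls8 pair is assumed to vary like these and the p cannot tell a response of cls8 from noise of that pair. No probe set passed this limma test for the wild type (707 at an unadjusted p under 0.05) or for sfr6 (669), and 947 had an unadjusted p under 0.05 for cls8.

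All 4 nuclear-encoded photosynthesis genes measured were lower at 4 °C in the wild type and higher at 4 °C in cls8. RCA, the activase of Rubisco, read 4093 and 2952 in the wild type and 2524 and 4003 in cls8, and the antenna gene LHCB4.1 read 4433 and 2931 in the wild type and 3418 and 4351 in cls8. The median difference of the log2 folds, cls8 minus the wild type, was 1.01, and this difference was not tested. The arrays may differ in how far their brightest probe sets reach, since 3 other nuclear genes as bright (PYK10, AT1G09310 and AT2G45180) had a median difference of 0.641, and quantile normalization left 0.18 for the photosynthesis genes and -0.11 for the others. A line difference in photosynthesis genes stays open for the part of the difference beyond that of the other bright genes.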

How the results depend on the processing

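The fits without both arrays of the third line for the sfr6, cls8 and list tests were chosen after seeing the data, and the other alternatives were planned. The temperature count of 2570 ranged from 1528 to 2292 without arrays (1528 and 1533 without the sfr6 array at 20 °C and 4 °C, 1529 without both) and was 1445 with no filter and 1589 with no genotype block. The sfr6 count of 183 ranged from 65 to 411 without arrays (409 without both cls8 arrays, with all 183 probe sets shared), and was 18 with no filter and 0 with no temperature term. The cls8 count of 16 ranged from 14 to 27 without arrays, and was 4 with no filter, 9 with the 60th percentile filter and 1 with no temperature term. Without a filter more probe sets are tested, and the prior and intensity trend of the variances are fitted over them too, so that each p changes. How much each of these moved the counts was not tested. Without a temperature term the cold response enters the residual. The causes of the other shifts were not tested. Of the 66 list tests 11 passed, and 0 with an estimated inter-gene correlation, where 2 residual degrees of freedom leave little room to pass. With no filter 14 of 81 passed, 10 of them shared, with the 60th percentile filter 11 of 57, and in the other settings 11 or 12 of 66. SWEET in sfr6 had an adjusted p of 0.276 with no filter and 0.0513 without both cls8 arrays. All 24 named genes of the temperature comparison kept their call in every fit without arrays, and 23 kept it in every other setting in which they were tested (all 8 settings for 19 of the 24, and 6 or 7 for the others), with AT5G62360 lost without the genotype block. For sfr6 10 of 20 named genes kept their call in every fit without arrays, and for cls8 8 of 11. All of them lost it with no temperature term. No named gene of these comparisons reversed. Probe sets at least 2-fold different in the cold, 478 in the wild type, 386 in sfr6 and 406 in cls8, numbered 711, 597 and 626 with no pseudocount, and 282, 216 and 229 with the median as pseudocount, which shrinks folds of dim probe sets by construction. With quantile normalization the CBF regulon difference of cls8 was -0.0597 (0.12 without it) and the nuclear photosynthesis difference of sfr6 reversed to -0.0155 (0.39 without it). The cause was not tested. Single values of the line differences stayed close in 368 cases and moved in 19. The pseudocount limits what dim probe sets can show.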

Other observations

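The tests of the CBF regulon without a pseudocount and for an own cold response of sfr6, the counts of genes picked in cls8, the fit of SWEET without the cls8 arrays and the weighing of the plastid transcripts were chosen only after the results were seen.

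The ATG8 family, whose proteins build the autophagosome, was lower at 4 °C. Of 9 measured members 6 fell (8 passed when adjusted over the list alone) and none rose, with log2 differences in limma of -1.13 ± 0.09 for ATG8E and -0.95 ± 0.14 for ATG8F, which read 1146 and 460.9 at 20 °C and 4 °C in the wild type. The family's median was -0.48 (camera adjusted p = 1.39e-04, and adjusted p = 0.868 with an estimated correlation). Cell-wall loosening genes moved both ways. Of 17 measured expansins and XTH genes 6 rose and 2 fell at 4 °C, with EXLA2 at 1.21, EXLA1 at 1.17 and XTH19 at 0.99, and with EXPA8 at -1.32 (camera adjusted p = 0.152 for the list). Of 24 measured UDP-glycosyltransferases 4 rose and 2 fell. Those that rose included UGT78D2 at 1.403 and UGT78D1 at 0.84, which glycosylate flavonoids, and UGT84A3 at 0.93, and the list did not pass (camera adjusted p = 0.175).

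Of 7 histone genes measured, HTB1, HTB2 and HTB11, which encode histone H2B, rose at 4 °C, with HTB1 at 0.95 ± 0.14 (limma), and the list had a camera adjusted p of 0.183. Of 10 measured genes of chlorophyll and haem synthesis PORB fell by 1.16 and HEME1 by 0.45 on the log2 scale, and 8 did not pass (camera adjusted p = 0.151). Of 14 SWEET sugar transporters with a named probe set 6 were kept by the filter. Of these, SWEET2 rose by 0.73, SWEET17 rose by 0.35 and SWEET16 fell by 0.61 at 4 °C. In sfr6 no SWEET gene passed limma over all probe sets (3 passed when adjusted over the list alone). The list had a median of -0.30 (camera adjusted p = 0.0303, and adjusted p = 0.704 with an estimated correlation). That list no longer passed without both cls8 arrays (camera adjusted p = 0.0513). Of 7 tubulin genes TUB9 rose by 0.56 while TUB5 and TUB6 fell by 0.54 and 0.32 at 4 °C. ARR15, a response regulator of cytokinin signalling, rose by 1.398, WRKY6 rose by 0.86 and XERICO, a RING protein linked to abscisic acid, fell by 0.73 on the log2 scale.

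Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probe sets past the limma threshold for temperature as the real one, which was the real split itself, with 2570 against a highest of 0 in the others. The other splits leave the temperature difference in the residual, and 10 splits are too few for a share under 0.05.

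The cold response of the CBF regulon was smaller in sfr6 than in the wild type for each of its 5 measured members, by a median of -0.44. Compression by the pseudocount was argued against by a median of -0.45 without one. A generally weaker response of the sfr6 arrays was not excluded. Against 233 other probe sets raised at least 2-fold in cls8, the list's median lay at the 9.85 percentile of random sets of 5, inside the middle range set for this test. The 233 had a median of -0.11, so a shortfall of that size would cover only a part of the list's. DI21 and COR47 of the list, at 0.42 and 0.99 in cls8, did not reach the 2-fold bar themselves. A loss of SFR6, the difference the design names, stays open as well, since the lowest adjusted p of a member in the limma test of an own cold response of sfr6 was 0.448, for COR15A, with 1 residual degree of freedom. A smaller response in sfr6 was seen in 139 of these 233 probe sets (59.7%) and in 31 of the 47 raised at least 4-fold (66.0%), and in 122 of 170 (71.8%) and 22 of 23 (95.7%) of those at least 2-fold and 4-fold lower at 4 °C in cls8.

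As a list, plastid-encoded transcripts were lower in cls8, with 3 of 69 passing limma, a median of -0.56 at 20 °C and one of -0.12 at 4 °C (camera adjusted p = 5.41e-26, and adjusted p = 0.414 with an estimated correlation). A difference in how far the brightest probe sets reach was argued against for the 35 dimmer transcripts, whose differences less those of the 20 nuclear probe sets nearest in level had a median of -0.632 at 20 °C and -0.504 at 4 °C. For the 34 brighter ones that explanation stays open at 20 °C, where the median of these excesses was -0.198 but the difference of the medians was -0.28, so that the share of their median of -0.50 it covers is not settled, and at 4 °C their median was 0.08 with an excess of -0.10, negative for 28 of 34. Less carry-over of RNA without a poly(A) tail into the labelling may account for the 20 °C part, where the 25S control of cls8 was at 0.177 of the wild type. At 4 °C, where that control was not lower, the median of -0.115 lay below 0 by more than 2 SD of random lists (SD 0.0327). That SD treats genes as independent. By the same measure sfr6 at 20 °C, with its control at 0.942 of the wild type, had a median of -0.144 (SD 0.0328). The 4 °C median of the whole list therefore cannot decide for or against carry-over. The 35 dimmer transcripts had a median of -0.447 in cls8 at 4 °C and of -0.046 in sfr6 at 20 °C. For the 34 brighter ones these medians were 0.075 and -0.187. Each value rests on 1 array per line, so the dimmer transcripts do not settle it for themselves either. A decrease of organelle transcripts of every kind stays open. The 7 kept probe sets of the mitochondrion-encoded list, out of 23, had a median of -0.271 (-0.36 at 20 °C, at the 0.01 percentile of random lists, and -0.18 at 4 °C, at the 9.62 percentile). The cls8 mutation, which was not tested apart from the repeat run of its arrays, stays open as well.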
